A study of Mus musculus with 20 samples.

How the data were processed

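The data are gene-level read counts of 20 RNA-seq libraries, 5 for each of 4 groups: GRflox and CardioGRKO mice at ZT0 and at ZT12. Per the labels' protocols, total RNA of the left ventricular free wall was isolated after perfusion with Tyrode solution. Poly(A)-enriched libraries were made, per the same protocols, with an Illumina TruSeq RNA kit and sequenced on an Illumina NovaSeq with paired-end reads of 75 bases. Genotype and time were taken from the labels of each library, and the replicate number from its title. The deposited values are whole-number counts per gene that had not been normalized. Per the submitters' processing notes, the tools named are STAR 2.5.1, featureCounts of Subread 1.5.1 and DESeq2 1.38.3, with the genome build mm10. Whether the counting used strand, how it treated reads that match several genes, and which annotation release it used are not given in the sources used here. Genes that overlap, lie antisense to each other or share sequence with a close copy can therefore have shared or lost reads, and the counts of a gene sum its transcripts.

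Each table had 24918 lines, all with a gene name. Lines of 1 gene at several loci were summed by Entrez identifier, which gave 24059 genes. This touched 369 genes, which held at most 0.03% of a library's counts. Of the identifiers, 99.6% (23969) matched the reference gene table of GRCm38.p6, the assembly also called mm10, from which coordinates were taken. No read was counted for 4768 genes, and mitochondrially encoded genes were not analysed here. The depth ran from 5854462 to 37648421 counts per library, with a median of 23223656. The shallowest library, replicate 1 of CardioGRKO at ZT0, also carries another number in its deposited file than the remaining 19. What that number means is not given in the sources used here, so its depth and whatever the number marks cannot be told apart. Within every group, pairs of replicates differed by more than sampling noise: chi-square per gene was 4.22 to 20.96 over genes with at least 20 counts. No pair thus looked like repeated deposits of 1 library, which does not show that the libraries come from separate animals.

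The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, on the counts as deposited. TMM factors ran from 0.961 to 1.040. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14007. A model of group means was fitted to all 20 libraries so that the groups share 1 estimate of spread, and the common biological coefficient of variation was 8.8%. The contrasts were CardioGRKO minus GRflox at each time, ZT12 minus ZT0 in each genotype, and the interaction. Standard errors of log2 fold changes were computed as the size of the change over the square root of F. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. CPM values are scaled by TMM, and log2 CPM used a prior count of 2. Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which tests whether a list's genes move one way on balance and compares them with no other genes. Camera looks for a shift of a list one way against the other genes, and lists said below to stand apart or not are meant in this sense. Fry also has a form that ignores direction, given here only for the core clock between genotypes. Of 34 lists, 32 with at least 3 measured genes were tested, and their p-values were adjusted within each comparison. Scores of a list are the mean over its genes of log2 CPM minus the gene's mean over all libraries. For the core clock, each gene was signed by its mean time difference over both genotypes. Differences of scores were tested with 2-sided exact permutation tests. Interaction calls were also counted with limma on log2 CPM for shuffled residuals of an additive model. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

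The model tests, the gene lists, the first group of alternatives below and the rule for naming genes were fixed before the data were examined. The score tests and the shuffled residuals were chosen after the fits had been seen. The rule names Nr3c1, the 8 genes with the largest rise and the 8 with the largest fall in each comparison, and up to 4 genes with the smallest p of each list discussed. The core clock list may be named in full. The 16 genes of a comparison needed an adjusted p under 0.05, a mean log2 CPM of at least 1 and, except for the interaction, no overlap between the libraries compared. Genes with provisional names (Gm with a number, or ending in Rik) were passed over. The rule allows 381 results, of which 61 lost their call in at least 1 alternative; list members given with values were picked with this known, so those printed held better than the rest. Glul and Ccdc69 were chosen after their values were seen. A gene that the rule names is not reported here.

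The code was tested on simulated counts drawn for the real genes from the real means, depths and trend of dispersion. The simulated counts lacked the scatter of single genes around that trend. In CardioGRKO at ZT12, 200 genes were changed, and 20 more were shifted 1.25-fold as a list. All of these were drawn from genes with a mean log2 CPM of at least 1. At 13911 simulated genes, changes of 1.25, 1.5, 2 and 3-fold were recovered for 52%, 84%, 100% and 100% of genes in the comparison of genotypes at ZT12, for 66%, 90%, 100% and 100% in the comparison of times in CardioGRKO, and for 18%, 76%, 98% and 100% in the interaction. Of 13691 unchanged genes, 10, 12 and 7 were called in these 3. Among simulated genes with a mean log2 CPM of at least 1, changes under 1.5-fold were thus often missed, above all in the interaction.

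Alternatives fixed in advance were RLE size factors in place of TMM, no filter beyond 1 read, a filter of CPM of at least 1 in at least 5 libraries, the replicate number as a block, DESeq2 1.42.0, fits of only the groups compared, and leaving out each library in turn. Thinning every library to the shallowest total, TMM factors without the 10 most abundant genes, and list tests at ZT0 without the shallowest library were added after seeing the data. The thinning was 1 random draw and was not repeated.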

Results

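RNA was sequenced from the free wall of the left ventricle of adult male C57BL/6 mice aged about 9 to 13 weeks, in a 2 × 2 design of genotype and time of day with 5 libraries per group. CardioGRKO mice carry floxed alleles of the glucocorticoid receptor gene Nr3c1 and a Cre recombinase driven by the alpha myosin heavy chain promoter, which is active in cardiomyocytes. GRflox mice are their littermates with the floxed alleles and no Cre, so the loss of the receptor and the presence of Cre were not separated by these groups. Hearts were taken at ZT0, when the lights went on, or at ZT12, when the lights went off. The series title names the cardiomyocyte glucocorticoid receptor and transcriptional rhythms of the heart as its subject. The 20 libraries held 5854462 to 37648421 counted reads (median 23223656). The shallowest was replicate 1 of CardioGRKO at ZT0, and the next held 11143527. In a principal component analysis PC1 (24.4% of the variance) separated the genotypes and PC2 (18.7%) the times. On PC1 that shallowest library lay at 34.5 and the remaining 4 of its group between 15.8 and 19.0. Its deposited file also carries another number than those of the other 19, with a meaning not given in the sources used here. The labels number the replicates without tying them to named animals, so the p-values below measure the spread between libraries. Of the annotated genes, 14007 passed the expression filter and were tested. Log2 fold changes are given ± their standard error, with 5 libraries in each group, and CPM values as the mean ± SD of 5 libraries.

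Nr3c1 (Entrez gene 14815, chromosome 18, 39410545 to 39519421 in mm10), the targeted gene, was lower in all CardioGRKO libraries than in any GRflox library. Its level was 115 ± 6.11 CPM in GRflox and 55.2 ± 3.51 CPM in CardioGRKO at ZT0, and 107 ± 7.98 against 51.0 ± 3.50 CPM at ZT12. The log2 fold change was -1.06 ± 0.06 at ZT0 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.04e-11) and -1.08 ± 0.06 at ZT12 (adjusted p = 5.17e-12). The reads counted over the whole gene come from all cell types of the wall, and the deleted part was not examined separately. Time of day did not move Nr3c1 past the threshold, with -0.10 ± 0.06 in GRflox and -0.12 ± 0.06 in CardioGRKO (edgeR, adjusted p = 0.256 and 0.255).

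The comparison of genotypes at ZT0 asks what the ventricle without the cardiomyocyte receptor expressed at lights on. In CardioGRKO 10 of 13 fetal and stress genes of the cardiomyocyte were higher, and 11 of 29 glucocorticoid-induced and 13 of 25 oxidative phosphorylation genes were lower. Camera called these lists, but not with an estimated correlation (adjusted p = 0.255, 0.327 and 0.255 with an estimated correlation). Casq1, the calsequestrin of skeletal muscle, rose 5.16-fold, from 25.1 ± 5.17 to 129 ± 7.49 CPM. Ogdhl, an oxoglutarate dehydrogenase-like enzyme, fell 5.50-fold, from 240 ± 17.5 to 43.9 ± 5.79 CPM. Kcnv2, a modifier subunit of voltage-gated potassium channels, fell 5.87-fold. Pfkfb1, an enzyme that sets the level of a regulatory fructose bisphosphate that activates glycolysis, fell 5.25-fold.

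By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 2060 of the 14007 genes differed between genotypes at ZT0, 1031 higher and 1029 lower in CardioGRKO. Most differences were small: 77.3% of the called genes changed by less than 1.5-fold, and 130 rose and 66 fell by at least 2-fold. Rankings by size here and below hold within the naming rule, which asks for a mean log2 CPM of at least 1 and, except in the interaction, no overlap between the libraries compared; some genes outside it rose more. Within it, the largest rises besides Casq1 were those of Blk (2.26 ± 0.15), Slc9a3 (2.12 ± 0.32), Klhdc7a (2.03 ± 0.12), Acta1 (1.80 ± 0.30), Ankrd1 (1.80 ± 0.21), Meig1 (1.76 ± 0.13) and Cpxm2 (1.74 ± 0.22). After Kcnv2, Ogdhl and Pfkfb1 the largest falls were those of Cngb3 (-2.15 ± 0.20), Csdc2 (-2.10 ± 0.13), Ptgds (-1.95 ± 0.26), Ankrd63 (-1.88 ± 0.29) and Myot (-1.86 ± 0.12), the last coding for the Z-disc protein myotilin. The count was 1636 without the shallowest library, and 1241 when all libraries were thinned to its depth, an alternative chosen after seeing the data.

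Among 13 measured fetal and stress genes of the cardiomyocyte, 10 were higher and 1 was lower at ZT0, with the same numbers adjusted over the list alone. Ankrd1, a stress-induced partner of titin, rose 3.47-fold, and Acta1, the skeletal alpha-actin, 3.48-fold. The fast-muscle myosin-binding protein gene Mybpc2 (1.13 ± 0.12), the matricellular gene Ctgf (1.10 ± 0.15) and Uchl1 (0.86 ± 0.12) rose as well. The list stood above other genes (camera, adjusted p = 5.40e-08), but not with an estimated correlation between its genes (adjusted p = 0.255 with an estimated correlation). Of 29 glucocorticoid-induced genes, 11 were lower and the other 18 did not pass (12 lower adjusted over the list alone). Arrdc2 (-1.49 ± 0.27), Ptgds (-1.95 ± 0.26), Hif3a (-1.85 ± 0.34) and the metallothionein gene Mt1 (-0.78 ± 0.15) fell, and the list was lower by camera (adjusted p = 2.53e-05, and adjusted p = 0.327 with an estimated correlation).

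The metabolic lists moved by small amounts and mostly downward at ZT0. In oxidative phosphorylation 13 of 25 genes were lower (18 adjusted over the list alone). They included Uqcrc1 (-0.30 ± 0.04), Cox6a2 (-0.41 ± 0.06), Sdhb (-0.22 ± 0.04) and Atp5c1 (-0.20 ± 0.04), which code for subunits of complexes III, IV and II and of the ATP synthase. Of 28 genes of fatty acid oxidation 15 were lower and 1 was higher (19 and 1 adjusted over the list alone). Acot1 (-1.51 ± 0.18), Eci1 (-0.37 ± 0.05) and Etfb (-0.33 ± 0.05) fell, and the uncoupling protein gene Ucp2 rose (0.83 ± 0.10). Of 21 genes in the list of branched-chain amino acid catabolism 10 were lower (13 adjusted over the list alone). Bckdhb stood at -0.49 ± 0.07, Aldh6a1 at -0.44 ± 0.06, Pcca at -0.27 ± 0.05, and Prodh, which breaks down proline, at -0.77 ± 0.11. Camera called all 3 lists lower (adjusted p = 1.32e-08, 1.89e-08 and 6.12e-07), and with an estimated correlation each had an adjusted p = 0.255. Lipid synthesis genes were lower in 10 and higher in 1 of 28 (the same numbers adjusted over the list alone; camera adjusted p = 0.0118, and 0.255 with an estimated correlation), including Agpat3 (-0.39 ± 0.05), the lipid droplet gene Plin5 (-0.53 ± 0.07) and Lpin1 (-0.38 ± 0.06). In glucose metabolism 7 of 26 were lower and 2 higher (10 and 4 adjusted over the list alone), and the list did not stand apart (camera, adjusted p = 0.0959). The glycogen synthase gene Gys1 fell (-0.36 ± 0.07). Without the shallowest library 10 genes were lower in oxidative phosphorylation, 14 in fatty acid oxidation and 10 in branched-chain amino acid catabolism. In lipid synthesis 8 were lower without it, and in glucose metabolism 5.

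Genes of excitation and calcium cycling went both ways at ZT0. Of 26 cardiac ion channel genes, 8 were higher and 7 lower (8 and 8 adjusted over the list alone; camera, adjusted p = 0.84). The T-type calcium channel gene Cacna1h (1.04 ± 0.10) rose, and Kcnj3 (-0.68 ± 0.08) fell. Of 20 calcium handling genes, 2 were higher and 8 lower (3 and 8 adjusted over the list alone; camera, adjusted p = 0.103), and without the shallowest library 5 were lower. Ryr2, the calcium release channel, fell from 2637 ± 247 to 2031 ± 138 CPM. Trdn (-0.34 ± 0.06) and Cacna1c (-0.27 ± 0.05) fell too, and Casq2, the cardiac calsequestrin, rose (0.27 ± 0.06).

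Markers of cell types moved beside the metabolic genes. Of 12 endothelial markers 5 were lower at ZT0 (7 adjusted over the list alone), with Pecam1 at -0.19 ± 0.04 and Cdh5 at -0.18 ± 0.04 (camera, adjusted p = 0.00238, and 0.255 with an estimated correlation). Of 11 cardiomyocyte markers, 9 of which stand in another list as well, 6 were lower and 1 higher (7 and 2 adjusted over the list alone; camera, adjusted p = 0.00187, and 0.255 with an estimated correlation). Of 10 pericyte and smooth muscle markers 5 were lower and 1 higher (7 and 1 adjusted over the list alone; camera, adjusted p = 0.00829, and 0.451 with an estimated correlation), the 1 being Acta2 (1.14 ± 0.14), a smooth muscle actin. Without the shallowest library 3 of the 10 were lower. The mean of the fibroblast markers differed by 0.03 on the log2 scale (2-sided exact permutation test, p = 0.667, Benjamini-Hochberg adjusted over 8 such tests 0.889) and that of macrophage markers by 0.02 (exact p = 0.905, adjusted 0.952).

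**Figure D1:**
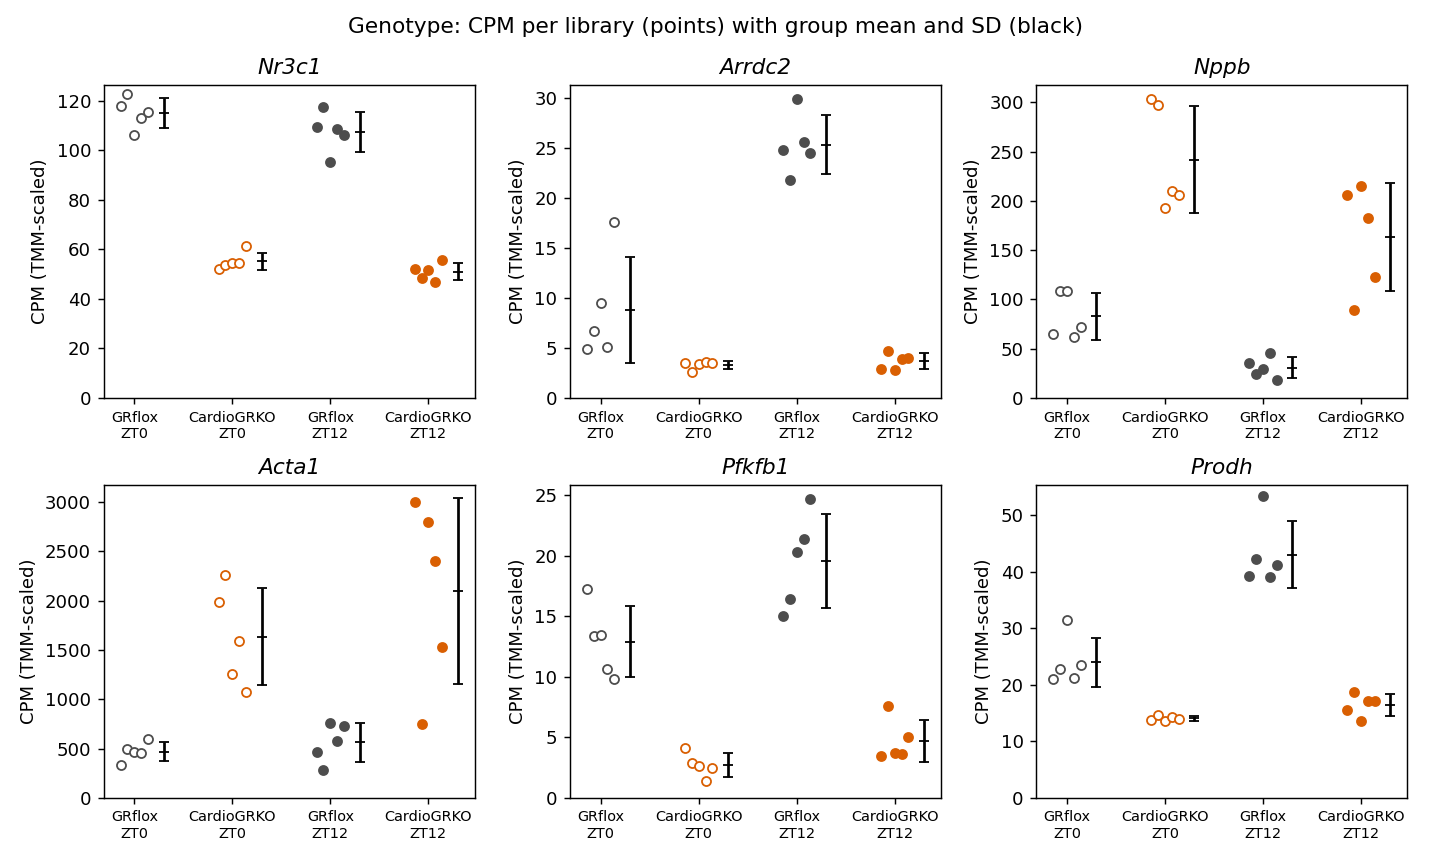
CPM of 6 named genes in each library (points), with the group mean and SD in black, for GRflox (grey) and CardioGRKO (orange) at ZT0 (open) and ZT12 (filled). Nr3c1 separates the genotypes at both times, at 115 and 107 CPM in GRflox against 55.2 and 51.0 CPM in CardioGRKO.

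The same comparison was made at ZT12, at lights off. In CardioGRKO 9 of 13 fetal and stress genes were higher, and 15 of 29 glucocorticoid-induced and 24 of 25 oxidative phosphorylation genes were lower. Camera called these lists too, but not with an estimated correlation (adjusted p = 0.141, 0.113 and 0.112 with an estimated correlation). Natriuretic peptide Nppb rose 5.31-fold, from 30.9 ± 10.6 to 163 ± 55.0 CPM, and Casq1 5.37-fold. Arrdc2 fell 6.95-fold, from 25.3 ± 2.94 to 3.68 ± 0.815 CPM, and Ptgds, the prostaglandin D synthase, fell 6.91-fold. Prodh fell 2.64-fold, from 43.1 ± 5.96 to 16.4 ± 1.96 CPM.

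In all, 2952 genes differed at ZT12 by the edgeR quasi-likelihood test, 1453 higher and 1499 lower in CardioGRKO, of which 168 and 113 changed by at least 2-fold and 76.1% by less than 1.5-fold. Within the naming rule, the largest rises besides Casq1 and Nppb were those of Blk (2.35 ± 0.15), Slc9a3 (2.27 ± 0.31), Klhdc7a (2.19 ± 0.12), Sec14l5 (2.06 ± 0.17), Ndnf (2.04 ± 0.10) and B3galt2 (1.94 ± 0.14). Kcnv2 (-2.94 ± 0.17), Arrdc2 (-2.80 ± 0.25), Ptgds (-2.79 ± 0.25), Ogdhl (-2.61 ± 0.10), Ankrd63 (-2.56 ± 0.27), Csdc2 (-2.35 ± 0.13), Myot (-2.15 ± 0.11) and Phyhd1 (-2.14 ± 0.11) had the largest falls. With libraries thinned to the shallowest total, chosen after seeing the data, 1903 genes were called.

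At ZT12 15 of 29 glucocorticoid-induced genes were lower in CardioGRKO (16 adjusted over the list alone), among them Arrdc2, Ptgds, the lipid droplet gene Plin4 (-0.84 ± 0.08) and Zbtb16 (-1.67 ± 0.16), a transcription factor gene induced by glucocorticoids (camera, adjusted p = 1.81e-09, and 0.113 with an estimated correlation). Of the fetal and stress genes 9 of 13 were higher and 1 lower, also adjusted over the list alone, with Mybpc2 at 1.23 ± 0.12, Ankrd1 at 1.56 ± 0.21 and Acta1 at 1.90 ± 0.30 (camera, adjusted p = 6.32e-06, and 0.141 with an estimated correlation). Acta1 spanned 744 to 3002 CPM among the CardioGRKO libraries at ZT12.

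Oxidative phosphorylation genes were lower at ZT12 in 24 of 25 cases, also adjusted over the list alone, with Uqcrc1 at -0.37 ± 0.04, Cox6a2 at -0.50 ± 0.06, Sdhb at -0.27 ± 0.04 and Atp5c1 at -0.30 ± 0.04 (camera, adjusted p = 3.23e-14, and 0.112 with an estimated correlation). In fatty acid oxidation 20 of 28 genes were lower and 1 higher, also adjusted over the list alone. Eci1 (-0.42 ± 0.05), the lipoprotein lipase gene Lpl (-0.42 ± 0.05) and Etfb (-0.35 ± 0.05) fell and Ucp2 rose (0.94 ± 0.10; camera, adjusted p = 1.07e-09 for the list, and 0.141 with an estimated correlation). In the list of branched-chain amino acid catabolism 17 of 21 were lower (19 adjusted over the list alone). Prodh, the member that breaks down proline, stood at -1.40 ± 0.10, Bckdhb at -0.66 ± 0.07, Aldh6a1 at -0.57 ± 0.06 and Pcca at -0.34 ± 0.05 (camera, adjusted p = 6.53e-12 for the list, and 0.112 with an estimated correlation). Glucose metabolism genes were lower in 14 and higher in 3 of 26 cases, also adjusted over the list alone. Among them were Pfkfb1 (-2.08 ± 0.21) and the glycogen branching enzyme gene Gbe1 (-0.36 ± 0.05; camera, adjusted p = 7.78e-04 for the list, and 0.113 with an estimated correlation). Of 28 lipid synthesis genes 8 were lower and 2 higher (8 and 6 adjusted over the list alone), with Lpin1 at -0.59 ± 0.06, and the list did not stand apart (camera, adjusted p = 0.315).

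Foxo3 (-0.83 ± 0.07), the mitophagy receptor gene Bnip3 (-0.67 ± 0.07) and Sesn1 (-0.60 ± 0.06) were lower at ZT12, and 7 of 21 genes of autophagy and protein breakdown were lower in all (7 lower and 1 higher adjusted over the list alone; camera, adjusted p = 0.00192, and 0.118 with an estimated correlation). Sarcomere genes were lower in 9 and higher in 1 of 19 cases (11 and 3 adjusted over the list alone), including Tnni3 (-0.34 ± 0.04) and Tcap (-0.51 ± 0.09; camera, adjusted p = 0.0089 for the list, and 0.141 with an estimated correlation). Of the calcium handling genes 10 of 20 were lower and 2 higher, also adjusted over the list alone, with Ryr2 at -0.56 ± 0.06, Trdn at -0.43 ± 0.06 and Cacna2d1 at -0.45 ± 0.08 (camera, adjusted p = 0.0395, and 0.286 with an estimated correlation). Gja1, which codes for the gap junction protein connexin 43, was at 498 ± 67.1 CPM in GRflox and 985 ± 44.1 CPM in CardioGRKO at ZT12, against 878 ± 22.1 and 1091 ± 58.0 CPM at ZT0. Of 26 ion channel genes 8 were higher and 10 lower at ZT12 (9 and 11 adjusted over the list alone; camera, adjusted p = 0.752), Cacna1h (1.26 ± 0.10) and Kcnj3 (-0.89 ± 0.08) among them. Matrix genes were higher in 7 and lower in 1 of 28 cases (11 and 1 adjusted over the list alone). Tgfb3 stood at 0.26 ± 0.06, Tgfb2 at 0.46 ± 0.11 and Loxl2 at 0.39 ± 0.09 (camera, adjusted p = 0.0126, and 0.737 with an estimated correlation).

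Endothelial markers were lower at ZT12 in 6 of 12 cases (7 adjusted over the list alone), with Pecam1 at -0.22 ± 0.04 and Esam at -0.29 ± 0.05 (camera, adjusted p = 2.08e-04, and 0.113 with an estimated correlation). Cardiomyocyte markers were lower in 8 and higher in 1 of 11 cases (9 and 2 adjusted over the list alone; camera, adjusted p = 2.53e-05, and 0.112 with an estimated correlation). Acta2 was again higher (0.93 ± 0.14), while 2 of the 10 pericyte and smooth muscle markers were lower (6 adjusted over the list alone; camera, adjusted p = 0.0914). The mean of the fibroblast markers differed by 0.07 on the log2 scale (2-sided exact permutation test, p = 0.357, adjusted 0.571) and that of macrophage markers by -0.01 (exact p = 0.952, adjusted 0.952).

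**Figure D2:**
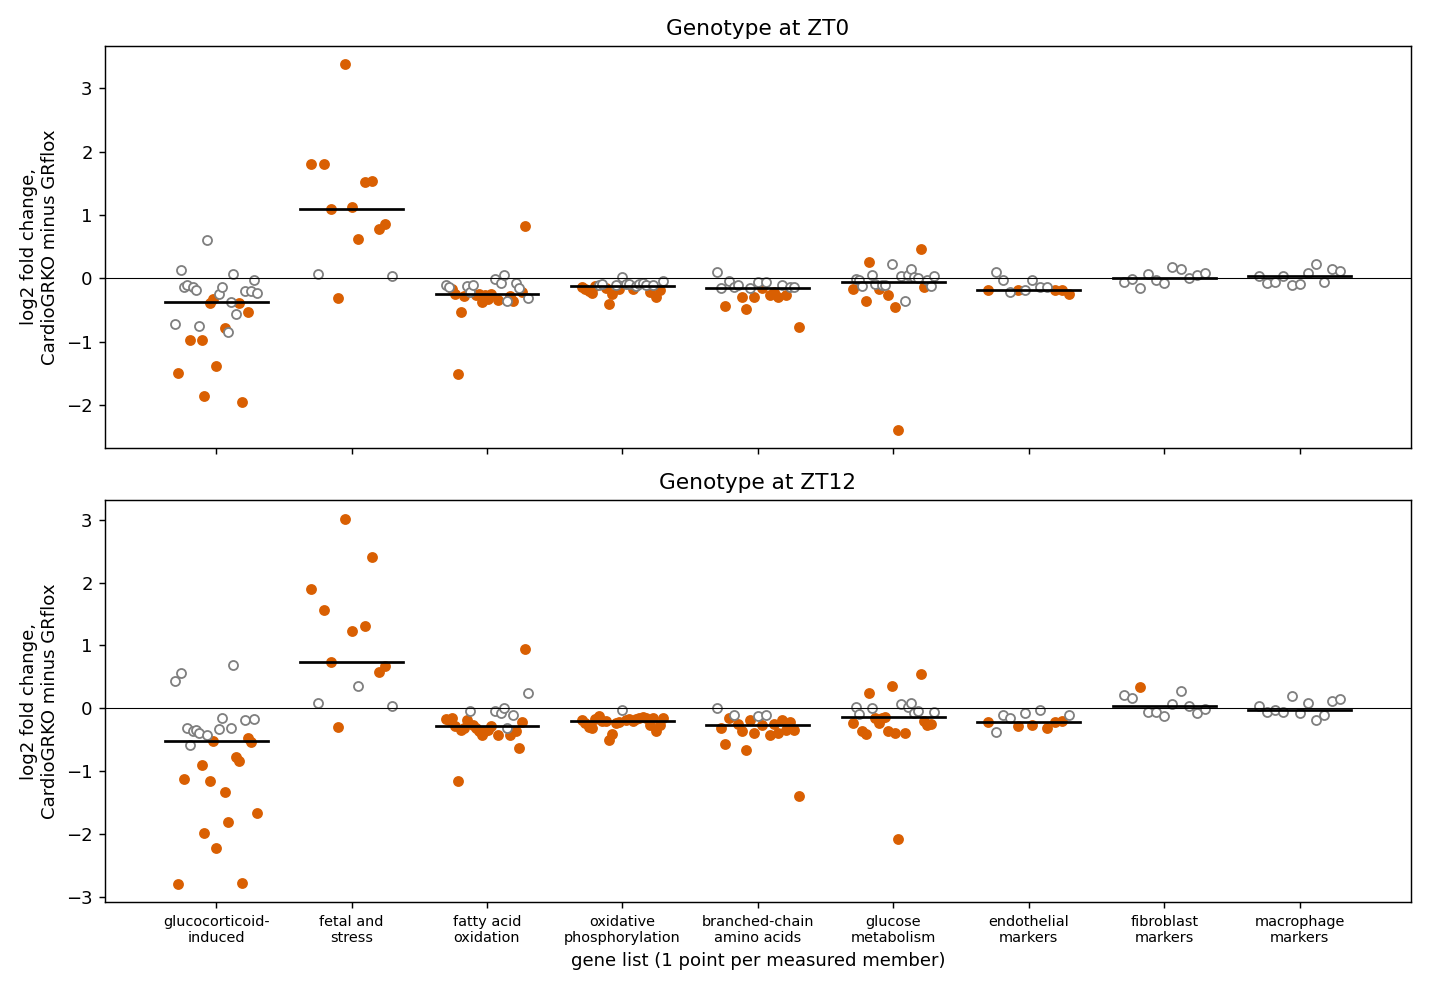
Log2 fold change of CardioGRKO over GRflox for every measured member of 9 gene lists (1 point per gene) at ZT0 and ZT12, filled where the edgeR adjusted p was under 0.05, with the list median as a bar. The medians of the fetal and stress list are 1.10 and 0.73, and those of oxidative phosphorylation -0.12 and -0.20.

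The genotype effects at ZT0 and ZT12, which share no libraries, were alike across genes: their log2 fold changes had a Pearson correlation of 0.76 and a Spearman correlation of 0.65 over 14007 genes, which are not independent replicates. Of the genes called at both times 756 were higher at both and 753 lower at both, where independent lists would share 106.9 and 110.1. Only 3 genes were called in opposite directions, and they are named here after their values were seen. Dbp was 2.06-fold higher at ZT0 (1.04 ± 0.13) and lower at ZT12 (-0.32 ± 0.10), Glul, the glutamine synthetase gene, was higher at ZT0 (0.25 ± 0.08) and lower at ZT12 (-0.39 ± 0.08), and Ccdc69 was lower at ZT0 (-0.37 ± 0.11) and higher at ZT12 (0.35 ± 0.11). Dbp at ZT0 and Glul at ZT12 kept their calls in all alternatives, and the other calls were lost in some. By edgeR, Dbp at ZT12 stood at -0.21 with an adjusted p = 0.0789 without CardioGRKO replicate 1, and at -0.30, -0.29 and -0.30 (adjusted p = 0.0582, 0.0635 and 0.0549) without GRflox replicates 2, 4 and 5. Glul at ZT0 lost its call without GRflox replicates 1, 2 or 4 or CardioGRKO replicates 1 or 2 (edgeR adjusted p up to 0.0974), or with only the groups compared (0.0504). Ccdc69 lost its call at ZT0 without GRflox replicates 2 or 3 or CardioGRKO replicates 1, 3 or 5 (edgeR adjusted p up to 0.0664), and at ZT12 without GRflox replicates 4 or 5 or CardioGRKO replicates 3 or 4 (up to 0.11), with thinned libraries (0.125) or with only the groups compared (0.0514).

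The clock genes themselves differed between genotypes. Of 19 core clock genes 5 were higher and 4 lower in CardioGRKO at ZT0 (7 and 5 adjusted over the list alone), and 2 were higher and 5 lower at ZT12 (3 and 6). Dbp (9.60 ± 0.731 against 19.9 ± 3.47 CPM), Per3 (8.58 ± 0.728 against 15.7 ± 2.55 CPM) and Bhlhe41 (0.59 ± 0.10) were higher in CardioGRKO at ZT0, and Arntl, which codes for the clock activator BMAL1, was lower (57.6 ± 4.0 against 37.3 ± 6.85 CPM). At ZT12 Npas2 (0.93 ± 0.20) and Bhlhe41 (0.47 ± 0.09) were higher, and Ciart (-1.57 ± 0.15), Tef (-0.36 ± 0.07) and Hlf (-0.48 ± 0.11) were lower. Ciart, a repressor of the clock activators, was also lower at ZT0 (-0.89 ± 0.23), a call that ended with thinned libraries (-0.75, edgeR adjusted p = 0.205). The list as a whole did not shift one way (camera, adjusted p = 0.602 at ZT0, where camera pointed up and the median was -0.02, and 0.457 at ZT12). Camera cannot see changes that go in opposite directions, as they did here. Fry without regard to direction gave adjusted p = 3.66e-09 at ZT0 and 5.42e-11 at ZT12, in a test that compares the list with no other genes.

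Time of day was compared within each genotype, ZT12 minus ZT0, to measure the day-night difference of the ventricle. In GRflox the clock output gene Dbp rose 20.7-fold, from 9.60 ± 0.731 to 198 ± 18.2 CPM, and Arntl fell 31.6-fold, from 57.6 ± 4.0 to 1.78 ± 0.416 CPM. Per2 rose 9.12-fold, Ciart 8.81-fold and Per3 7.44-fold. Of 29 glucocorticoid-induced genes 19 were higher and 2 lower at ZT12 (camera, adjusted p = 8.47e-09, and 0.231 with an estimated correlation), and Zbtb16 rose 6.02-fold and the metallothionein gene Mt2 5.83-fold. The collagen genes Col4a1 and Col4a2 and the elastin gene Eln fell.

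In GRflox 2423 genes differed between the times by the edgeR quasi-likelihood test, 1139 higher and 1284 lower at ZT12, and 77.8% of them changed by less than 1.5-fold (102 rose and 82 fell by at least 2-fold). Of 19 core clock genes 12 were higher and 5 lower (13 and 6 adjusted over the list alone), with Nr1d2 at 1.87 ± 0.09, Tef at 1.75 ± 0.08, Cry2 at 0.89 ± 0.07, Clock at -1.18 ± 0.06 and Npas2 at -2.40 ± 0.19 (camera, adjusted p = 3.14e-05, and 0.0698 with an estimated correlation). After Zbtb16 and Mt2, Chac1 (2.15 ± 0.29) and Rhobtb1 (2.02 ± 0.12) had the largest rises outside the clock under the naming rule, and Spon2 (-4.41 ± 0.20), Slc41a3 (-2.29 ± 0.14), Tmem171 (-2.15 ± 0.18), Col5a3 (-2.14 ± 0.10), Prdm1 (-1.92 ± 0.25) and Adam19 (-1.92 ± 0.16) the largest falls. Adjusted over the list alone, 19 glucocorticoid-induced genes were higher and 4 lower, with Klf15 at 0.99 ± 0.12, Mt1 at 1.11 ± 0.15 and Map3k6 at 1.44 ± 0.19. The count of called genes was 1485 with libraries thinned to the shallowest total, chosen after seeing the data.

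Autophagy and protein breakdown genes were higher at ZT12 in GRflox in 8 of 21 cases, also adjusted over the list alone. They were led by Foxo3 (0.90 ± 0.07), Sesn1 (0.70 ± 0.07), the autophagy receptor gene Sqstm1 (0.43 ± 0.07) and the autophagy kinase gene Ulk1 (0.38 ± 0.07; camera, adjusted p = 3.19e-05 for the list, and 0.0698 with an estimated correlation). Matrix genes were lower in 11 and higher in 1 of 28 cases (11 and 2 adjusted over the list alone). The lower ones included the basement membrane collagens Col4a1 (-0.75 ± 0.08) and Col4a2 (-0.64 ± 0.07), Col15a1 (-0.89 ± 0.11) and elastin, Eln (-1.16 ± 0.14; camera, adjusted p = 0.046 for the list, and 0.903 with an estimated correlation). Genes of the unfolded protein response were lower in 8 and higher in 2 of 17 cases (9 and 2 adjusted over the list alone). Manf (-1.03 ± 0.14) and Xbp1 (-0.56 ± 0.08) fell and Herpud1 (1.03 ± 0.08) rose, and the list did not stand apart (camera, adjusted p = 0.0817). The Z-disc gene Tcap rose 3.30-fold and Gja1 fell 1.76-fold. Endothelial genes went both ways, 2 higher and 6 lower of 12 (3 and 7 adjusted over the list alone; camera, adjusted p = 0.387), with Ly6c1 at 0.73 ± 0.07, the VEGF receptor gene Kdr at -0.78 ± 0.10 and the tight junction gene Cldn5 at -0.92 ± 0.14.

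In CardioGRKO clock genes differed between ZT0 and ZT12 as well. Dbp rose 8.07-fold, from 19.9 ± 3.47 to 159 ± 27.4 CPM, Per2 6.04-fold, Ciart 5.47-fold and Per3 4.10-fold, and Arntl fell 13.9-fold, from 37.3 ± 6.85 to 2.61 ± 0.837 CPM. Of 29 glucocorticoid-induced genes 11 were higher and 2 lower, also adjusted over the list alone (camera, adjusted p = 1.75e-04, and 0.675 with an estimated correlation). Fam107a stood at 2.29 ± 0.32, Fkbp5 at 1.76 ± 0.26, Map3k6 at 1.35 ± 0.20 and Zbtb16 at 1.15 ± 0.17. Spon2, which codes for a secreted matrix protein, fell 15.1-fold.

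By the edgeR quasi-likelihood test 1284 genes differed between the times in CardioGRKO, 619 higher and 665 lower at ZT12, 77.5% of them by less than 1.5-fold (56 rose and 57 fell by at least 2-fold). The core clock list had 12 higher and 4 lower of 19 (13 and 6 adjusted over the list alone), with Tef at 1.17 ± 0.08, Clock at -0.93 ± 0.06 and Npas2 at -1.49 ± 0.17 (camera, adjusted p = 1.69e-05, and 0.0581 with an estimated correlation). The remaining large changes were those of Adh1 (1.81 ± 0.19), Mt2 (1.58 ± 0.46), Col5a3 (-1.93 ± 0.10), Slc41a3 (-1.75 ± 0.14), Foxs1 (-1.59 ± 0.17), Ccnjl (-1.57 ± 0.20) and Cx3cr1 (-1.47 ± 0.26). Of these the call of Mt2 ended by edgeR without CardioGRKO replicates 3, 4 or 5 of ZT0 or 1 or 3 of ZT12 (adjusted p up to 0.087) and with thinned libraries (0.138). With libraries thinned to the shallowest total, chosen after seeing the data, 763 genes were called.

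Unfolded protein response genes were lower at ZT12 in CardioGRKO in 8 and higher in 1 of 17 cases (9 and 1 adjusted over the list alone). Among them were the chaperone gene Hspa5 (-0.54 ± 0.09), Manf (-0.81 ± 0.14) and Xbp1 (-0.45 ± 0.08; camera, adjusted p = 0.0209 for the list, and 0.852 with an estimated correlation). Of 28 matrix genes 6 were lower and 1 higher (7 and 3 adjusted over the list alone; camera, adjusted p = 0.594, pointing down beside a median of 0.02), with Eln at -1.14 ± 0.14, Col4a1 at -0.42 ± 0.08 and Col15a1 at -0.59 ± 0.11. Calcium handling genes were lower in 3 of 20 cases (4 adjusted over the list alone; camera, adjusted p = 0.0317, and 0.675 with an estimated correlation). In autophagy and protein breakdown 2 of 21 were higher (3 adjusted over the list alone; camera, adjusted p = 0.0621), Sqstm1 (0.35 ± 0.07) and Ulk1 (0.36 ± 0.07). Tcap rose 2.26-fold. Endothelial genes went both ways again, 3 higher and 5 lower of 12, also adjusted over the list alone (camera, adjusted p = 0.0873), with Ly6c1 at 0.56 ± 0.07, Kdr at -0.67 ± 0.10 and Cldn5 at -1.40 ± 0.14.

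The time differences of the genotypes, which share no libraries, had a Pearson correlation of 0.69 and a Spearman correlation of 0.62 across the 14007 genes, which are not independent replicates. Of the genes called in both genotypes 429 were higher at ZT12 in both and 528 lower in both, where independent lists would share 50.3 and 61.0. A gene called in GRflox and not in CardioGRKO is not thereby shown to differ, which is what the interaction tests.

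**Figure D3:**
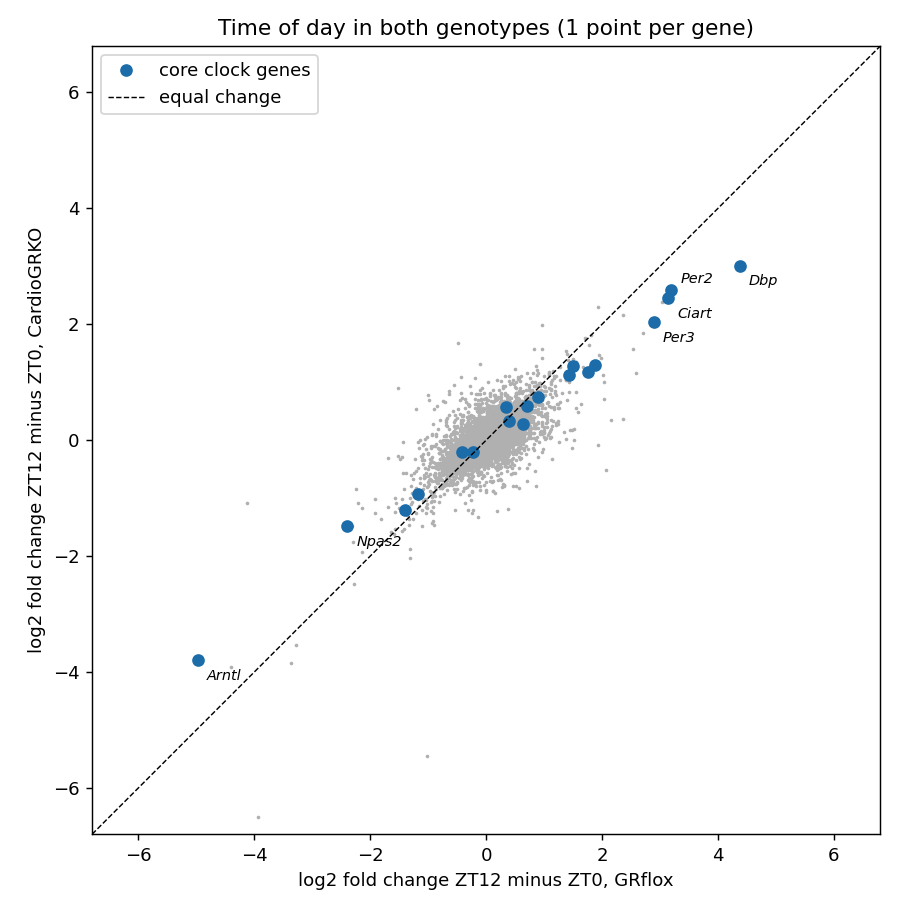
Log2 fold change of ZT12 over ZT0 in GRflox (horizontal) and CardioGRKO (vertical) for the 14007 tested genes (grey, 1 point each), with the 19 core clock genes in blue and those beyond 2 in GRflox named. Points between the dashed line of equal change and the horizontal axis, such as Dbp (4.37 and 3.01) and Arntl (-4.98 and -3.80), changed less in CardioGRKO.

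The interaction of genotype and time, the ZT12 minus ZT0 difference in CardioGRKO minus that in GRflox, asks which day-night differences depended on genotype. Dbp, Per3, Pik3r1, Foxo3 and Gja1 had a smaller time difference in CardioGRKO. Dbp differed by -1.36 ± 0.16 and Per3 by -0.86 ± 0.16. Pik3r1, the regulatory subunit of phosphoinositide 3-kinase, went from 185 ± 10.7 to 396 ± 64.9 CPM in GRflox and from 116 ± 7.33 to 130 ± 12.7 CPM in CardioGRKO (-0.94 ± 0.12). Foxo3 went from 55.8 ± 3.22 to 104 ± 13.1 CPM in GRflox and from 50.2 ± 3.96 to 58.6 ± 3.16 CPM in CardioGRKO (-0.69 ± 0.10).

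By the edgeR quasi-likelihood test 26 genes passed, 9 with a higher and 17 with a lower interaction value. Of the 14007 genes 839 had an unadjusted p under 0.05, a bound that genes without an interaction pass at a rate of about 0.05. In 25 of the 26 the time difference was smaller in size in CardioGRKO, the exception being Zfp646. Gja1 (0.67 ± 0.09, edgeR adjusted p = 5.29e-04) fell from ZT0 to ZT12 by 0.82 in GRflox and its change in CardioGRKO was -0.15. The lower interaction values included Zbtb16 (-1.44 ± 0.24), Rnf144b (-0.85 ± 0.14), Herpud1 (-0.73 ± 0.11), Tef (-0.58 ± 0.11), Sesn1 (-0.57 ± 0.09) and Glul (-0.64 ± 0.11, named after its values were seen), and the higher ones Tnfaip2 (0.56 ± 0.10) and Fbxw7 (0.49 ± 0.08). Nr3c1 itself did not pass (-0.02 ± 0.08).

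The number of interaction genes depended on the libraries and the tool. It was 17 without replicate 2 of GRflox at ZT0, 17 without replicate 4 of that group, 17 without replicate 4 of GRflox at ZT12 and 16 without replicate 1 of CardioGRKO at ZT12, and 69 with DESeq2. Arntl (1.18 ± 0.24) lost its call in 12, Klhdc8a (0.67 ± 0.14) in 14, Leo1 (0.47 ± 0.10) in 18, Akap1 (0.33 ± 0.06) in 6 and Zfp646 (0.29 ± 0.06) in 16 of the 20 fits that left out 1 library. Over all alternatives, DESeq2 included, their adjusted p reached 0.71, 0.107, 0.221, 0.063 and 0.743. The value of Arntl was 0.68 with thinned libraries (edgeR adjusted p = 0.71), chosen after seeing the data, and 1.08 to 1.30 with 1 library left out. The thinning was 1 random draw, and Arntl had only 1.045 to 3.322 CPM in the ZT12 libraries. Sampling noise of that draw at low counts can thus have moved the value. Leo1 and Zfp646 also lost the edgeR call with RLE size factors (0.0528 and 0.0584). Rhobtb1 (-0.89 ± 0.17) lost it without replicate 2 or 4 of GRflox at ZT0, 5 of GRflox at ZT12 or 1 of CardioGRKO at ZT12 (edgeR adjusted p up to 0.0544). Ccrn4l (-0.70 ± 0.13), which codes for nocturnin, lost it without replicate 4 of GRflox at ZT12 or 1 of CardioGRKO at ZT12 (edgeR adjusted p = 0.0519 and 0.0517).

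As lists, the core clock had 1 higher and 3 lower interaction values past the threshold of 19 (3 and 4 adjusted over the list alone; median -0.14; camera, adjusted p = 0.0197, and 0.398 with an estimated correlation). Glucocorticoid-induced genes had 1 lower of 29 (6 adjusted over the list alone; median -0.19; camera, adjusted p = 1.22e-04, and 0.413 with an estimated correlation). Autophagy and protein breakdown had Foxo3 and Sesn1 as its 2 lower genes of 21, also adjusted over the list alone (median -0.08; camera, adjusted p = 2.95e-04, and 0.314 with an estimated correlation). A score of the clock was compared as well, a test chosen after seeing the data. The mean time difference of the 19 core clock genes, each signed by its mean direction over both genotypes, was 1.79 ± 0.05 (SE) on the log2 scale in GRflox and 1.35 ± 0.08 in CardioGRKO. The difference of -0.44 had p = 6.30e-05 in a 2-sided exact permutation test over 63504 relabellings of genotype within each time. Such relabellings test against no genotype difference at either time, and not against equal time differences alone. Of the 19 genes 18 had a smaller change in CardioGRKO, the exception being Nr1d1, which codes for the repressor REV-ERB alpha (interaction 0.24 ± 0.17, edgeR adjusted p = 0.93).

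**Figure D4:**
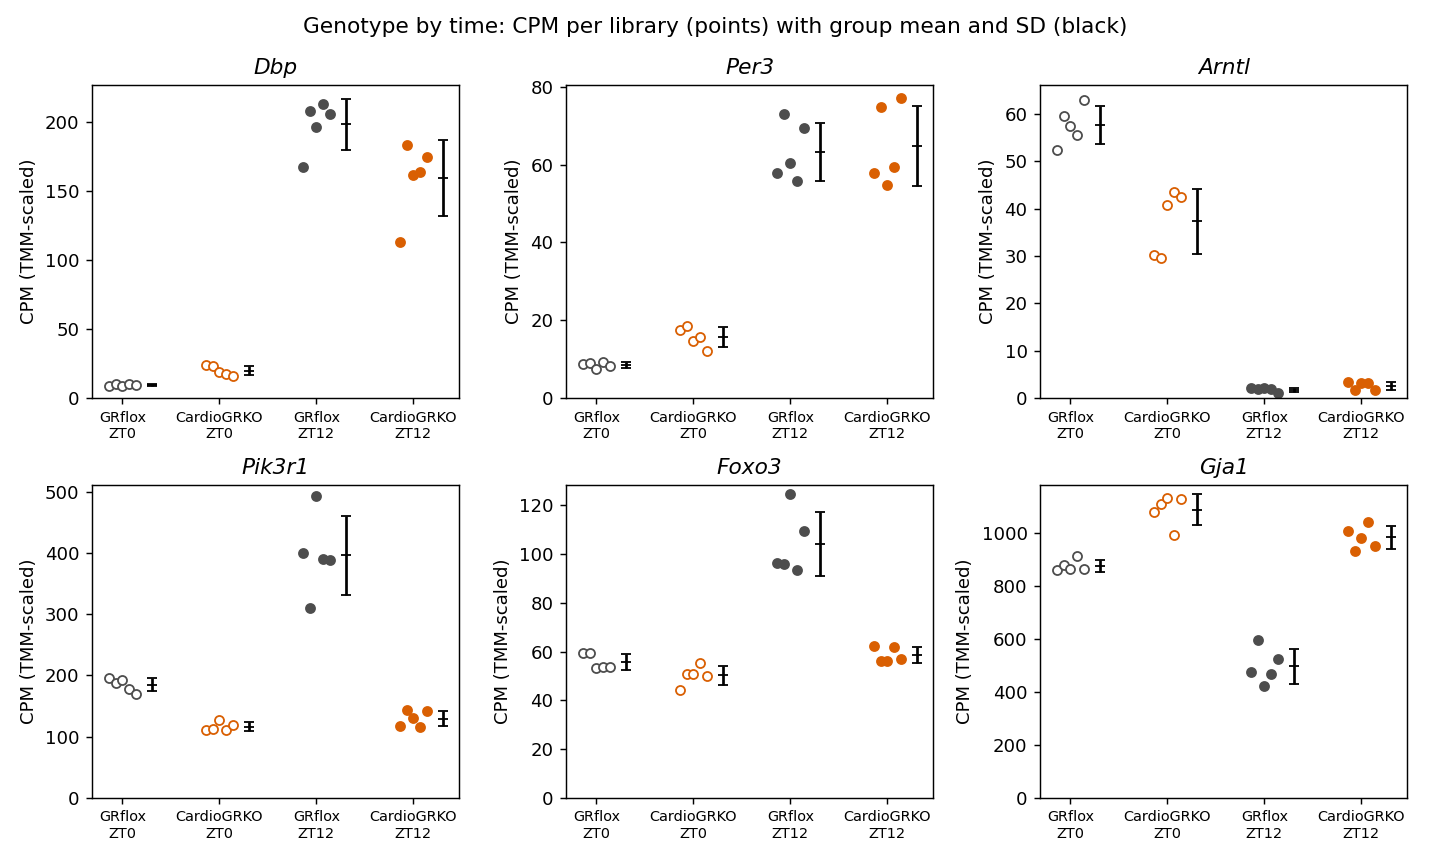
CPM of 6 genes past the interaction test in each library (points), with the group mean and SD in black, for GRflox (grey) and CardioGRKO (orange) at ZT0 (open) and ZT12 (filled). Pik3r1 and Foxo3 reach 396 and 104 CPM in GRflox at ZT12 against 130 and 58.6 CPM in CardioGRKO.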

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

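Of the tests in this part, those of clock scores, cell marker scores, scaling, thinning, shuffled residuals and the ratio of time changes were chosen after the results were seen.

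Between genotypes, 26 genes differed in their time difference by the edgeR quasi-likelihood test. Those named had interaction values, on the log2 scale, of 1.18 (Arntl, 0.68 with thinned libraries), 0.67 (Klhdc8a), 0.67 (Gja1), 0.56 (Tnfaip2), 0.49 (Fbxw7), 0.47 (Leo1), 0.33 (Akap1) and 0.29 (Zfp646). The lower ones were Zbtb16 (-1.44), Dbp (-1.36), Pik3r1 (-0.94), Rhobtb1 (-0.89), Per3 (-0.86), Rnf144b (-0.85), Herpud1 (-0.73), Ccrn4l (-0.70), Foxo3 (-0.69), Glul (-0.64, chosen after its values were seen), Tef (-0.58) and Sesn1 (-0.57). By camera with a preset correlation 9 lists differed in the interaction. Their median values were -0.14 for the core clock, -0.19 for glucocorticoid-induced genes, -0.10 for branched-chain amino acid catabolism, -0.08 for autophagy, and -0.05 for glucose metabolism. Medians of -0.06 were found for the sarcomere, for oxidative phosphorylation and for cardiomyocyte markers, and 0.12 for matrix genes. With an estimated correlation camera called 0 of these lists (2 of 32 at an unadjusted p under 0.05), and fry called 0 (5 at an unadjusted p under 0.05).

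Chance was tested with other splits of the compared libraries into groups of the same sizes, 100 per comparison with the real one included. In each of the 5 comparisons 1 of the 100 splits, the real one, gave as many calls. For the first 4 this argues against chance at this number of splits, on the condition that the libraries are independent, which the labels do not show. The real counts and the highest of the other splits were 2060 and 84 for genotype at ZT0, 2952 and 571 at ZT12, 2423 and 301 for time in GRflox, 1284 and 287 for time in CardioGRKO, and 26 and 4 for the interaction. Splits that mix the real groups carry a larger spread, which lowers their counts, and for the interaction this comes from the genotype effect itself, so its splits decide nothing. With the additive effects of genotype and time removed, the residuals were shuffled over the libraries. Limma then called 20 interaction genes for the real groups and at most 1 in any other of 100 shufflings, the real one included. This argues against chance there too, on the same condition.

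The clock score rose less from ZT0 to ZT12 in CardioGRKO than in GRflox, with a difference of -0.44 (2-sided exact permutation p = 6.30e-05, 63504 relabellings). With any 1 library left out the difference was -0.39 to -0.48. The relabellings mix genotype within each time, so that p is against no genotype difference at either time. The shallowest library is argued against as the source, since without it the difference was -0.44 (exact permutation p = 6.30e-05). A library labelled with the wrong time also finds no place, since the lowest ZT12 score of CardioGRKO lay 1.02 above its highest ZT0 score, with a largest range within a group of 0.33. A smaller swing and a shifted phase cannot be told apart, because hearts were taken at only 2 times of day, although 18 of the 19 genes changed less in CardioGRKO. Loss of the receptor in cardiomyocytes remains a hypothesis, and the presence of Cre, which goes with it in every library, stays open.

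Genes in the lists of oxidative phosphorylation, fatty acid oxidation and branched-chain amino acid catabolism were lower in CardioGRKO at both times, 38 of 74 at ZT0 and 61 at ZT12, with 37 lower at both. The last list also holds Prodh, which breaks down proline. Without the shallowest library 10, 14 and 10 genes of these lists, in the order given, were lower at ZT0. A lower share of cardiomyocytes alone would raise the markers of every other cell type alike. The endothelial score instead was -0.13 at ZT0 and -0.19 at ZT12 (exact permutation p = 0.00794 each, the smallest that 252 relabellings gave, and 0.0317 adjusted over 8 tests). The endothelial minus fibroblast score was -0.16 at ZT0 and -0.26 at ZT12 (exact p = 0.0238, adjusted 0.0476 each). These values argue against a lower share of cardiomyocytes alone. They cannot decide on a lower share of cardiomyocytes and endothelial cells together, since the cardiomyocyte markers were lower as well. None of the 12 endothelial, 4 of the 11 fibroblast and 9 of the 11 cardiomyocyte markers stand in another list, and the most abundant endothelial and fibroblast genes had 428 and 368 CPM (Cdh5) and 1482 and 1365 CPM (Gsn) in GRflox and CardioGRKO at ZT12. With factors computed without the 10 most abundant genes 61 genes were lower at ZT12 and 37 at ZT0, but these factors moved the 3 lists by a median of only 0.001 and 0.005, against a standard error of 0.055, so scaling set by a few abundant genes was hardly tested. That scaling stays open, as do a lower share of cardiomyocytes and endothelial cells together, loss of the receptor, Cre, and a change within the remaining cells.

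Fewer genes were called between the times in CardioGRKO than in GRflox, a ratio of 1.89 of the counts. Depth is argued against, since the ratio was 1.95 with all libraries thinned to the same total. A larger spread with changes of the same size is argued against too: over 1767 genes picked by their mean time effect in both genotypes, the median CardioGRKO change was 0.79 of the GRflox change (0.76 to 0.85 with any 1 library left out), and 70.9% changed less. The ratio was 0.77 and 0.78 with the threshold of that choice at 3 and 5 in place of 4 standard errors. The biological coefficient of variation was 9.2% in CardioGRKO and 8.3% in GRflox. The main model shares 1 estimate of spread, so this difference could hardly lower the CardioGRKO count there. Fits of only the groups compared, each with its own estimate, called 2476 genes in GRflox and 996 in CardioGRKO, and there a larger spread can add to the difference. Loss of the receptor and Cre stay open.

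Single libraries that stood apart from the other 4 of their group were looked for in 123 named genes and in library depth. Dixon's test passed in 26 of 496 tests, 5.2%, where chance gives about 5%. In GRflox at ZT0 the values were 1138 CPM for Ankrd1 in replicate 5 (607 to 753 in the others), 4.14 for Meig1 in replicate 4 (3.0 to 3.31), 31.5 for Prodh in replicate 3 (21.1 to 23.4), and 3068 for Ryr2 in replicate 3 (2450 to 2581). In GRflox at ZT12 they were 30.4 CPM for Casq1 (18.4 to 20.9) and 1465 for Uqcrc1 (1540 to 1553) in replicate 1, 56.2 for Ccrn4l in replicate 2 (68.2 to 71.3), and 53.4 for Prodh (39.1 to 42.3) and 1263 for Glul (1071 to 1099) in replicate 3. Replicate 4 of that group had 1451 CPM for Ankrd1 (1012 to 1125), 141 for Sesn1 (168 to 176) and 259 for Kdr (177 to 190), and replicate 5 had 54.9 for Kcnj3 (49.1 to 50.2) and 1.04 for Arntl (1.84 to 2.03). In CardioGRKO at ZT0 they were 3.29 CPM for Sec14l5 (5.74 to 6.72) and 32.9 for Cirbp (23.9 to 25.6) in replicate 1, 2.57 for Arrdc2 (3.39 to 3.61) and 20.9 for Per2 (6.28 to 10.3) in replicate 2, and 61.1 for Nr3c1 in replicate 5 (51.9 to 54.5). In CardioGRKO at ZT12 they were 6.68 CPM for Tmem171 in replicate 1 (4.18 to 4.73), and 207 for Plin4 (246 to 260), 62.1 for Per2 (73.6 to 76.4), 951 for Col4a2 (717 to 770) and 252 for Kdr (170 to 189) in replicate 3. Replicate 5 of that group had 2.42 CPM for Cngb3 (1.10 to 1.38) and 6.97 for Sec14l5 (5.04 to 5.44).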

How the results depend on the processing

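Thinning to the shallowest total, factors without the 10 most abundant genes and list tests without the shallowest library were added after seeing the data, and the other alternatives were planned. With all libraries thinned, 1241 genes were called for genotype at ZT0, 1903 at ZT12, 1485 for time in GRflox and 763 for time in CardioGRKO, of which 1153, 1763, 1367 and 703 were shared with the full counts; lower depth is the alternative's own construction. The interaction count was 33 with thinned libraries, 21 of them shared, and Arntl fell there from 1.18 to 0.68. The interaction count was 69 with DESeq2, which included all 26, and the cause was not tested. Leaving out 1 library gave 1636 to 1968 genes for genotype at ZT0, 2498 to 2872 at ZT12, 1931 to 2252 for time in GRflox, 874 to 1371 for time in CardioGRKO and 16 to 33 for the interaction. The interaction count was 17 without replicate 2 or 4 of GRflox at ZT0 or replicate 4 of GRflox at ZT12, and 16 without replicate 1 of CardioGRKO at ZT12. RLE factors, the other filters, factors without the 10 most abundant genes and fits of only the groups compared kept each count within 1.5 times. No scaling moved the median log2 fold change by over 0.03.

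Of the 214 named results, 4050 fits under the alternatives gave 3936 with the outcome and direction kept, 109 with a call lost and 5 reversed. A result that had not passed, such as Nr3c1 over time, counted as kept while it still did not pass. A fit without an adjusted p would count as kept as well. The losses fell on 13 results, 7 of them in the interaction, and the cause was not tested. The reversed ones are those of Nr3c1 in the interaction, which had not passed at -0.02: 0.01 with thinned libraries, without GRflox ZT0 replicate 3, without CardioGRKO ZT0 replicate 5 and without CardioGRKO ZT12 replicate 4, and 0.02 without GRflox ZT12 replicate 2. Leaving out 1 library gave -0.06 to 0.02. All lie within its standard error of 0.08, and the cause was not tested. The correlations of the genotype effects and of the time effects across genes were 0.81 and 0.76 over the 13017 genes with a CPM of at least 1 in at least 5 libraries.

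Camera with a preset correlation called 10, 13, 4, 4 and 9 of 32 lists in the 5 comparisons, in the order above. With an estimated correlation camera called 0 in each, with 5, 10, 3, 1 and 2 at an unadjusted p under 0.05. Fry, which compares a list with no other genes, called 13, 13, 5, 6 and 0 (14, 14, 9, 7 and 5 at an unadjusted p under 0.05). No list call by camera thus held with an estimated correlation. Without the shallowest library camera called the same 10 lists at ZT0.

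The labels give no pairing of the replicate numbers. Same-numbered libraries had correlations of their deviations from -0.40 to 0.34, with 7 of 20 over 0.1 and 8 of 20 correlating best with their own number, so they were not taken as pairs. Between genotypes at the same time, 9 of 10 were above 0, 5 over 0.1 and 6 best with their own number, where chance gives 2. Between times in a genotype these were 4, 2 and 2 of 10. Something shared by equal numbers within a time thus stays open. The block fits an effect of each number that is the same at both times, so it does not model a likeness within a time. With the replicate number as a block 2194, 3111, 2513, 1359 and 38 genes were called in the 5 comparisons, and 10, 13, 4, 5 and 9 lists. The list of corticosteroid receptors at ZT12 lost its camera call with the block (adjusted p = 0.0731 against 0.0462). Cell cycle genes at ZT12 gained one (0.0487 against 0.0673), as did macrophage markers for time in CardioGRKO (0.0411 against 0.0685). Among named genes Zfp646 lost its interaction call (edgeR adjusted p = 0.0551).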

Other observations

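The values in the first 2 paragraphs come from tests planned before, except those of the cell cycle score and of its list without a library, which like the glucocorticoid score were chosen after the results were seen, and the correlations of stress and metabolic scores were planned before theirs were seen.

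Cell cycle genes were higher in CardioGRKO in 4 of 18 cases at ZT0 (5 adjusted over the list alone; camera, adjusted p = 0.00187, and adjusted p = 0.577 with an estimated correlation) and in 3 of 18 at ZT12 (camera, adjusted p = 0.0673). At ZT0 the shallowest library, replicate 1 of CardioGRKO, had a cell cycle score of 1.32 on the log2 scale, against -0.28 to 0.24 in the other 4 of its group and -0.36 to -0.06 in GRflox. Without it the difference of the mean scores was 0.24 in place of 0.50, and 4 of 18 genes were higher (camera, adjusted p = 0.0373, and adjusted p = 0.593 with an estimated correlation). The cold-inducible RNA-binding gene Cirbp rose from ZT0 to ZT12 by 0.57 ± 0.10 (log2, SE) in GRflox and 0.67 ± 0.11 in CardioGRKO (edgeR quasi-likelihood, adjusted p = 3.92e-04 and 1.50e-04), and its list had only 2 measured genes. Heat shock and chaperone genes did not stand apart between genotypes (camera, adjusted p = 0.302 at ZT0 and 0.457 at ZT12). Nor did inflammation (0.881 and 0.713), interferon response (0.363 and 0.95) and immediate early genes (0.457 and 0.752, all camera adjusted p-values). The list of corticosteroid receptors and 11beta-HSD had 3 measured genes, and its lower member at both times was Nr3c1, the targeted gene. The test of that list thus holds the deletion itself (camera, adjusted p = 0.129 at ZT0 and 0.0462 at ZT12, the latter 0.286 with an estimated correlation).

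Macrophage markers were higher at ZT12 than at ZT0 in 3 of 11 cases in GRflox and in 2 of 11 in CardioGRKO, and the list did not stand apart (camera, adjusted p = 0.093 and 0.0685). Of 3 lymphocyte markers 1 was lower at ZT12 in both genotypes (camera, adjusted p = 0.37 and 0.0873). Between genotypes no call was made by camera for the atrial or conduction (0.576 at ZT0 and 0.309 at ZT12), Schwann cell and neuron (0.311 and 0.699), adipocyte (0.84 and 0.625), mesothelial (0.84 and 0.457), erythroid (0.881 and 0.953) and skeletal muscle lists (0.164 and 0.76). Casq1, the skeletal muscle calsequestrin, is not in the last list.

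Loss of the receptor in cardiomyocytes may take away part of the rise of glucocorticoid-induced genes toward ZT12. Their score rose by 0.75 on the log2 scale in GRflox and by 0.45 in CardioGRKO (2-sided exact permutation p = 0.00794 each, the smallest of 252 relabellings). The difference of -0.29 had a standard error of 0.18 and an exact permutation p = 0.409 over 63504 relabellings of genotype within time. This leaves the hypothesis open: the relabellings also mix the genotype difference within each time, which widens their spread, and a p over the threshold does not show that the rises were alike.

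Libraries with higher stress genes may have lower metabolic genes within a genotype. After time means were removed, the scores had a Pearson correlation of -0.70 over 10 CardioGRKO libraries (permutation p = 0.0414, 100000 resamples, 0.0828 adjusted over 2 genotypes; Spearman -0.72, p = 0.0246, adjusted 0.0492) and -0.55 over 10 GRflox libraries (permutation p = 0.104, adjusted 0.104; Spearman -0.67, p = 0.053, adjusted 0.053). Without the 2 farthest libraries they were -0.49 (permutation p = 0.199) and -0.21 (p = 0.506), and -0.61 in CardioGRKO without the shallowest library. By Pearson's r the relation failed the correction and rests on those libraries, though leaving out extremes also lowers r by construction; by Spearman's rho CardioGRKO passed narrowly, and the relation stays open. A missed threshold with 10 libraries does not bound the correlation, so the GRflox result, though it met the bound set beforehand for the absence of a relation, does not exclude it.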
